A study of Mus musculus with 78 samples.

How the data were processed

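Lineage-negative Kit-positive bone marrow cells of WT and KO mice given G-CSF or PBS were profiled as 4 single-cell libraries, and sorted HSC/MPP and GMP as ChIPmentation sets. ATAC and further H3K4me1 and H3K27ac sets came from WT GMP, and 78 samples are listed in all. Per the labels' protocols, the ChIPmentation mice received 5 ug of G-CSF daily for 2 days or PBS, and Kmt2c was deleted in KO. The single-cell labels give WT or KO, G-CSF or PBS (control) and the age, but no dose or days.

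The single-cell values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 6.1.1 on mm10 from a 10x 3' v3.1 kit, per the file headers and the submitters' processing notes. The deposited matrices hold called cells only, with 32285 genes and 14 antibody tags, 2 of them hashtags. Nothing in the labels ties a hashtag to an animal. Symbols shared by several gene identifiers (38) were kept apart by identifier. The deposited peak files hold, per the file headers and the submitters' processing notes, MACS2 broad peaks from BWA alignments (ChIPmentation) and MACS2 narrow peaks from Bowtie2 alignments (ATAC), on mm10/GRCm38. Versions and the calling threshold are not given in the sources used here; the lowest deposited -log10 p is 1. Raw reads were not used here. Per the file headers, peaks were called on pooled replicates, 4 per group except 3 for GMP H3K27ac of KO PBS, WT G-CSF and the reference, and 3 for ATAC. Each deposited peak carries a fold enrichment (a ratio) and a -log10 p and -log10 q, which are the authors' own and were used only to rank or filter within a set. HSC/MPP and GMP sets carry different experiment codes, so cell type and experiment cannot be told apart.

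Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Scrublet, the planned doublet caller, marked 1 cell in each G-CSF library (0.0151% and 0.0125%) against 169 and 349 in WT and KO PBS, and fell under the limit of 0.5% fixed in advance for a working caller. Barcodes with both hashtags (each with 20% to 80% of at least 10 hashtag UMIs) were removed in all libraries instead: 234 in WT PBS, 197 in WT G-CSF, 516 in KO PBS and 421 in KO G-CSF. Doublets within a hashtag remain. This rule was set after the data were seen. The 4 libraries were clustered together without integration: counts scaled per cell and log-transformed, 2000 variable genes (mitochondrial, haemoglobin, immunoglobulin and T cell receptor genes, Kmt2c, Xist and Y-linked genes left out), 30 principal components, 15 neighbours and Leiden clustering at resolution 1. A cluster was named by the list of fixed markers with the highest mean log2 fold, unless its 10 leading genes pointed elsewhere. At least 3 markers had to be detected. There were 2 clusters without a name, 1 because its best lists lay within 0.25 log2 of each other and 1 because its leading genes belonged to another list. That margin was set after the data were seen and was not varied. A cluster mostly of 1 library or treatment may be that library rather than a cell type.

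Counts were summed per library and class and given as CPM, the UMIs of a gene scaled to the usual fixed class total, with exact Poisson intervals, and shares of cells with exact Clopper-Pearson intervals, at 95% and for counting error only. Folds of counts have exact conditional intervals, and log2 ratios of shares a normal approximation. With 1 library per group no test between groups was made, and no p-value is given. Log2 ratios of (CPM + 5) were used for ranking and for lists. G-CSF folds in the text are ratios of CPM divided by the shift of the median gene, since that shift exceeded 0.1 log2 for G-CSF in both main classes. It did not between genotypes, so folds of KO against WT are ratios of CPM and were not divided. A fold against 0 UMIs is a lower bound against 3 UMIs. A list's median over members with at least 5 CPM in 1 library was set against 10000 random lists matched on expression in 20 bins, with an interval from 200 Poisson redraws of the counts. Single genes are the 12 highest and 12 lowest per comparison with at least 20 CPM, 30 UMIs and a 1.5-fold difference, without predicted, sex-linked, haemoglobin, mitochondrial, immunoglobulin and T cell receptor genes. Members of the fixed lists are named as well. Some genes that met these rules are not reported here. In peak comparisons the 3 peaks of highest fold that 1 set has and the other lacks were listed. The comparisons, these rules, 23 gene lists, 16 marker lists and the alternatives not said to be added were fixed before the data were examined; which of the lists and listed genes are described was chosen after their values were seen.

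Peaks on chromosomes 1 to 19 and X were merged within a set. Sets were compared by overlap of at least 1 bp and by the base-pair Jaccard index, with genes from GENCODE vM21 (21951 protein-coding genes). Enhancer-like peaks are H3K4me1 peaks over 1 kb from every TSS that overlap H3K27ac of the same group. The planned ratio of shared G-CSF regions to independent sets is left out, because regions found in all 4 sets raise it and can never differ with G-CSF. The shares over all regions in KO that enter it are given instead. Named loci reach 50 kb to each side of the TSS of 12 genes. Alternatives were stricter cell filters (1000 genes, 5% mitochondrial), doublets kept, resolutions 0.6 and 2, cell-cycle genes left out, thinning to 3000 UMIs, TMM factors from edgeR, DESeq2 size factors, a prior of 1 CPM, no filter on low counts, at least 50% of a peak covered, a -log10 q of at least 5, equal numbers of peaks and autosomes only. Added after the data were seen were Scrublet calls, shares without mature neutrophil-like cells, each hashtag's cells alone, HSC/MPP-like cells without the 10% richest in neutrophil UMIs, and the filter on low counts lifted for all genes. The alternative without that filter on low counts was read as lifting it for list members only, a reading settled after both sets of values were known. The gene step was tested on simulated data for G-CSF against PBS in WT HSC/MPP-like cells over 10460 genes, of which 200 were changed. All 12 highest and 12 lowest genes were truly changed, a raised list lay at percentile 100 and an unchanged one at 9.82, and 96.1% of intervals over 2000 genes held the true ratio. Overlaps of simulated peaks were exact for 1000 of 1000. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.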

Results

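Bone marrow progenitors of wild-type (WT) and KMT2C-deficient (KO) mice were compared after granulocyte colony-stimulating factor (G-CSF) or PBS. The labels give an age, 8 to 10 weeks, for the single-cell mice only. KMT2C is a histone methyltransferase that deposits H3K4me1, a mark of enhancers, and G-CSF is a cytokine that drives neutrophil production and releases haematopoietic stem cells (HSC) from marrow into blood. The series title frames the question as mobilization of HSC and granulocyte bias under G-CSF. All samples came from marrow, so cells already released were not measured. The single-cell part held 4 libraries of lineage-negative Kit-positive (Lin-Kit+) cells, 1 per genotype and treatment, in which RNA and 14 antibody tags were counted. The WT PBS library held 7194 barcodes and 112363138 UMIs, WT G-CSF 6829 and 109840794, KO PBS 8640 and 122449149, and KO G-CSF 8284 and 141574931. After filtering, 6671, 6447, 7538 and 7608 cells were kept in that order, at a median of 15022, 7329, 14117 and 7081.5 UMIs per cell. The chromatin part held 16 ChIPmentation peak sets (a ChIP method that adds sequencing adapters with a transposase) of H3K4me1 and H3K27ac, a mark of active enhancers and promoters, in HSC and multipotent progenitors (HSC/MPP) and in granulocyte-monocyte progenitors (GMP). It also held 2 reference sets and 1 set of open chromatin (ATAC) from WT GMP. Each library or pooled peak set stood alone in its group, so no difference has a check by replicate libraries or sets. The 2 hashtags of each library, which no label ties to animals, were compared only as an alternative added after the data were seen. The intervals given cover counting error only.

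Kmt2c transcripts were lower in both KO libraries. The level was 59.1 CPM (57.6 to 60.6) in WT PBS against 28.4 (27.4 to 29.4) in KO PBS, and 48.4 (47.1 to 49.7) in WT G-CSF against 26.1 (25.2 to 27.03) in KO G-CSF. In HSC/MPP-like cells it was 101 CPM (93.6 to 110) in WT PBS and 50.4 in KO PBS, and 67.2 in WT G-CSF and 49.9 in KO G-CSF. Mature neutrophil-like cells, nearly all from the G-CSF libraries, had 88.3 CPM in WT and 66.9 in KO. The 3' tags of the assay can lie outside the deleted part of the gene, so the remaining transcripts neither check nor contradict the deletion. Kmt2d, the paralogous methyltransferase, was 1.08-fold (0.858 to 1.37) higher in KO after PBS and 1.23-fold (0.982 to 1.54) higher after G-CSF in HSC/MPP-like cells. Kdm6a, the demethylase of the same complex, was 1.00-fold (0.826 to 1.22) lower and 1.19-fold (0.981 to 1.43) higher.

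**Figure D1:**
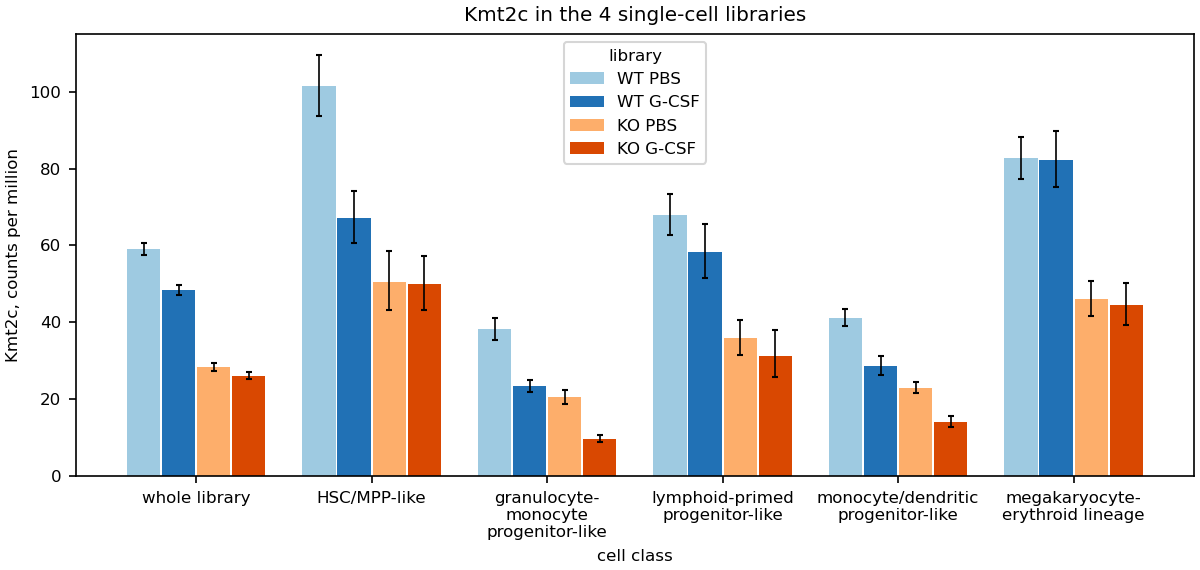
Kmt2c level in CPM (linear axis from 0) in the whole library and in 5 cell classes of the 4 libraries, with exact 95% Poisson intervals as error bars. Both KO libraries lie below the WT library of the same treatment, with 28.4 against 59.1 CPM after PBS and 26.1 against 48.4 after G-CSF in the whole library.

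G-CSF changed the make-up of the Lin-Kit+ sort in both genotypes. Cells with a mature neutrophil profile made up 64.2% (63.0 to 65.3) of WT G-CSF and 61.1% (60.04 to 62.2) of KO G-CSF cells, against 1 of 6671 cells in WT PBS and 2 of 7538 in KO PBS. Neutrophil progenitor-like cells went from 18.6% to 0.202% in WT and from 8.22% to 0.184% in KO, but at resolution 2.0 they made up 1.85% of WT G-CSF and 1.77% of KO G-CSF. HSC/MPP-like cells went from 11.4% (10.7 to 12.2) to 6.02% (5.45 to 6.63) in WT, a log2 ratio of -0.93 (-1.096 to -0.76), and from 6.31% (5.78 to 6.89) to 4.04% (3.60 to 4.50) in KO, a log2 ratio of -0.65 (-0.85 to -0.44). The granulocyte lineage (GMP-like plus neutrophil progenitor-like) had log2 ratios of -1.397 (-1.505 to -1.29) in WT and -0.62 (-0.71 to -0.54) in KO, and the megakaryocyte-erythroid lineage of -1.21 (-1.38 to -1.04) and -1.08 (-1.25 to -0.91). These 6 ratios turn when mature neutrophil-like cells are left out, an alternative added after the data were seen. HSC/MPP-like cells then went from 11.4% to 16.8% in WT and from 6.32% to 10.4% in KO, with log2 ratios of 0.55 and 0.72. The granulocyte lineage then gave 0.08 and 0.74, and the megakaryocyte-erythroid lineage 0.27 and 0.28. The sort on Kit bears on all shares: the median CD117 (Kit) tag count per cell was 203 in WT PBS, 65 in WT G-CSF, 182 in KO PBS and 45 in KO G-CSF, and it was 46 and 30 in the mature neutrophil-like cells of WT and KO G-CSF.

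Between genotypes, HSC/MPP-like cells were fewer in KO after both treatments, with log2 ratios against WT of -0.86 (-1.02 to -0.70) after PBS and -0.58 (-0.79 to -0.37) after G-CSF. The granulocyte lineage was lower in KO after PBS, 26.5% against 31.6% with a log2 ratio of -0.25 (-0.33 to -0.18), and higher after G-CSF, 17.2% against 12.01% with a log2 ratio of 0.52 (0.40 to 0.64). Within it, GMP-like cells were more frequent in KO after PBS (18.3% against 12.98%) and after G-CSF (17.0% against 11.8%), while neutrophil progenitor-like cells were fewer after PBS (log2 ratio -1.18 (-1.31 to -1.05)). Monocyte/dendritic progenitor-like cells made up 35.6% of KO PBS against 23.1% of WT PBS, and 7.36% of KO G-CSF against 5.79% of WT G-CSF. Lymphoid-primed progenitor-like cells had log2 ratios of -0.44 (-0.62 to -0.25) and -0.53 (-0.87 to -0.20), and the megakaryocyte-erythroid lineage had log2 ratios of -0.25 (-0.38 to -0.12) and -0.12 (-0.32 to 0.08), the second with an interval that spans 0. In each library the cells of 1 hashtag were high in Xist and those of the other in Y-linked genes, and their shares taken alone, an alternative added after the data were seen, were unlike in several of these comparisons. KO against WT then gave log2 ratios of 0.16 in high-Xist and 0.96 in high-Y cells for GMP-like cells after PBS, 0.043 and 0.66 for monocyte/dendritic progenitor-like cells after G-CSF, and -0.73 and -0.0011 for lymphoid-primed progenitor-like cells after PBS. HSC/MPP-like cells formed cluster 3 in all libraries, but GMP-like cells lay in clusters 6 and 10 after PBS and 7 and 11 after G-CSF, and monocyte/dendritic cells mostly in 2, 4 and 15 after PBS and 16 and 18 after G-CSF. Clusters 5 and 27 stayed unnamed by a rule set after the data were seen. They held 9.25% and 0.150% of WT PBS cells, 0.853% and 0.496% of WT G-CSF, 10.2% and 0.212% of KO PBS, and 0.486% and 0.631% of KO G-CSF.

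**Figure D2:**
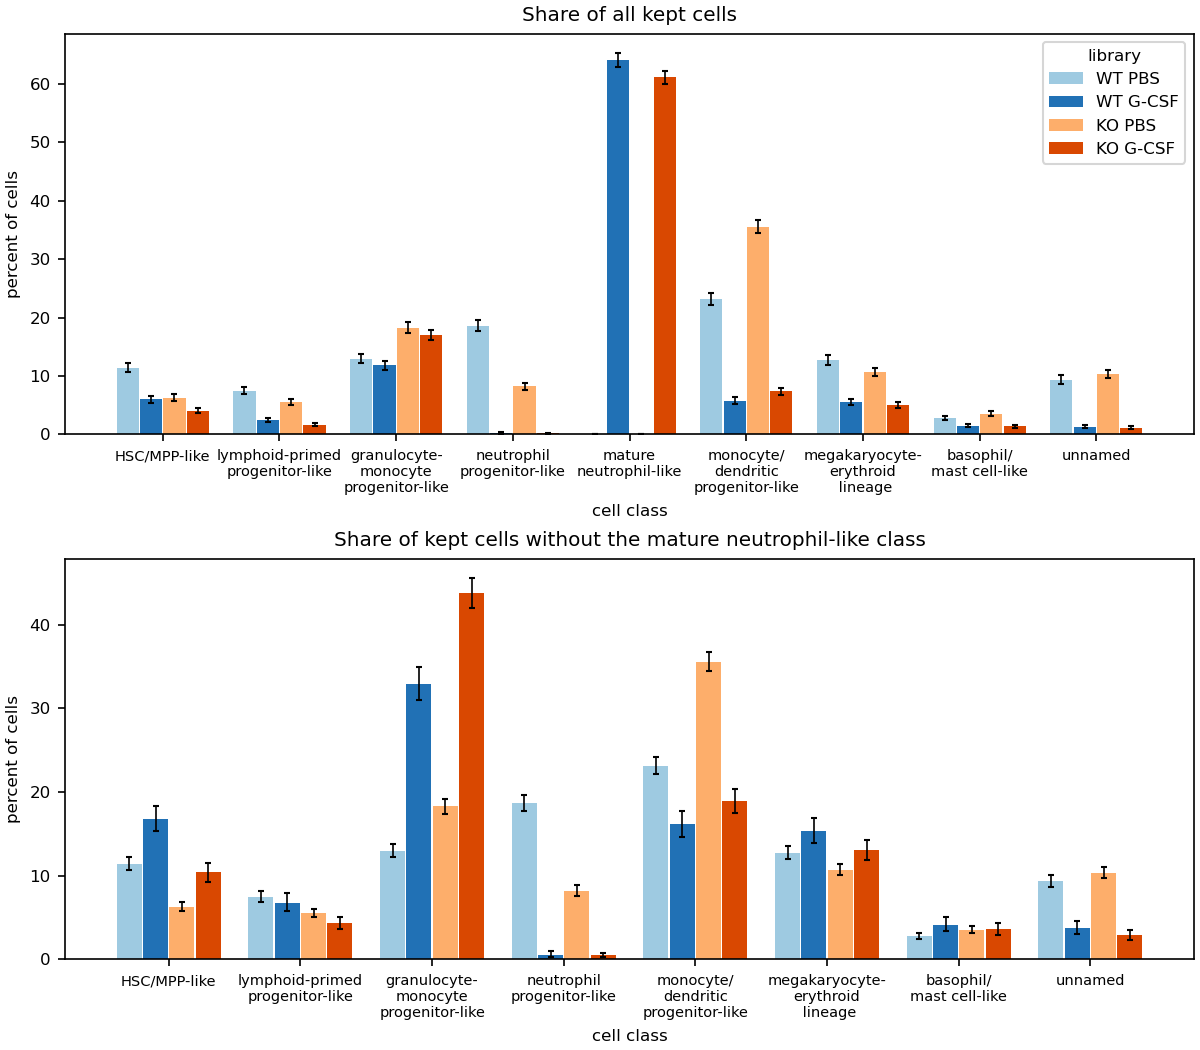
Share of cells per cell class (percent, axes from 0) in the 4 libraries, of all kept cells (upper panel) and without the mature neutrophil-like class (lower panel), with exact 95% binomial intervals as error bars. Mature neutrophil-like cells reach 64.2% and 61.1% in the G-CSF libraries, and HSC/MPP-like cells are lower in KO than in WT after both treatments.

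In HSC/MPP-like cells, G-CSF went with higher STAT3 target, oxidative phosphorylation and G2/M genes and lower stem cell and MHC class II genes in both genotypes. List medians and G-CSF folds below are relative to the median gene, which itself shifted by -0.23 log2 in WT and -0.13 in KO after G-CSF in this class, and by -0.20 and -0.15 in GMP-like cells. Between genotypes it shifted by less than 0.1 log2, and folds of KO against WT are plain ratios of CPM. Unlike in the whole libraries, cells of both classes held more UMIs after G-CSF. Median UMIs per HSC/MPP-like cell were 7505 in WT PBS, 13315 in WT G-CSF, 6806.5 in KO PBS and 12168 in KO G-CSF. Per GMP-like cell they were 20318.5, 48343, 16130 and 43499. An effect of this depth on the gene levels was not tested. The G-CSF receptor and STAT3 target list had a relative median log2 ratio of 0.44 (0.36 to 0.57) in WT and 0.46 (0.35 to 0.63) in KO, with 11 of 11 and 11 of 11 measured members above the median gene, and lay at percentiles 99.9 and 100 of 10000 random lists matched on expression. Socs3, a feedback inhibitor of STAT3 signalling, was 4.43-fold (3.73 to 5.29) higher in WT and 4.10-fold (3.22 to 5.26) in KO, and Il4ra 1.89-fold and 2.53-fold. Csf3r, the G-CSF receptor, was 1.72-fold and 1.83-fold higher, but its log2 ratio in KO was -0.02 without the 10% of cells richest in neutrophil transcripts and 0.18 with doublets kept. Ifitm1, an interferon-induced membrane protein, went from 514 to 2872 CPM in WT (6.56-fold (6.32 to 6.82)) and from 543 to 2417 CPM in KO (4.86-fold (4.62 to 5.11)). Meg3, an imprinted non-coding RNA, went from 4.35 to 60.6 CPM in WT and from 2.67 to 19.3 CPM in KO. Oxidative phosphorylation genes were higher, 0.65 (0.51 to 0.75) in WT and 0.57 (0.45 to 0.66) in KO, among them Cox5a (2.19-fold and 1.68-fold) and Cox4i1 (2.03-fold and 1.52-fold). G2/M genes were higher by 0.66 (0.49 to 0.82) in WT and 0.23 (0.10 to 0.36) in KO, with Mki67, a marker of cycling cells, 1.95-fold and 1.501-fold higher (log2 ratios 0.23 and 0.28 with doublets kept). At the finer Leiden resolution of 2.0 the G2/M value in KO was 0.04. S phase genes lay at 0.01 (-0.06 to 0.07) in WT and 0.23 (0.15 to 0.29) in KO, but in WT at -0.15 at resolution 2.0 and at -0.13 with the filter on low counts lifted for all genes.

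The stem cell maintenance list was lower after G-CSF, at -0.20 (-0.30 to -0.11) in WT and -0.20 (-0.33 to -0.07) in KO (4 of 17 and 5 of 17 members above the median gene; percentiles 0.310 and 0.140), and at resolution 2.0 the WT value was -0.07. Hlf, a stem cell transcription factor, was 1.29-fold (1.203 to 1.37) lower in WT and 1.60-fold (1.48 to 1.73) lower in KO. Egr1, an immediate early factor, was 3.35-fold and 3.31-fold lower. The megakaryocyte-biased stem cell list was at -0.40 (-0.55 to -0.21) in WT and -0.02 (-0.34 to 0.29) in KO, and Itga2b (CD41) was 2.01-fold and 2.38-fold lower. MHC class II genes were lower, -0.48 (-0.58 to -0.38) in WT and -0.27 (-0.42 to -0.12) in KO, with H2-Aa 3.29-fold and 1.86-fold lower, whereas Cd74, the invariant chain, was 1.02-fold higher in WT and 1.203-fold lower in KO. Mpo and Elane, granule proteins of early granulocyte progenitors, were 2.77-fold and 2.62-fold lower in WT and 3.07-fold and 1.98-fold lower in KO, as they also were in the whole libraries, and Angpt1, a ligand of the Tek receptor, 2.37-fold and 1.88-fold lower. Among lymphoid genes, Il7r, the interleukin-7 receptor, went from 8.69 to 37.2 CPM in WT and from 8.90 to 53.6 CPM in KO, and Dntt, a polymerase of early lymphoid cells, was 2.15-fold and 3.41-fold higher. The lymphoid priming list was at 0.18 (0.09 to 0.30) in WT and 0.54 (0.30 to 0.71) in KO, but turned to -0.06 and -0.05 at resolution 2.0, and to -0.01 in WT when the filter on low counts was lifted for all genes. With doublets kept, the log2 ratio of Il7r was 0.76 in WT and 0.40 in KO. Cxcr4, the receptor that retains stem cells in the marrow, was 1.06-fold (0.901 to 1.25) higher in WT and 1.95-fold (1.57 to 2.43) higher in KO.

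Transcripts of mature neutrophils also moved with G-CSF in this class. S100a9 went from 114 to 1579 CPM in WT and from 53.1 to 1965 CPM in KO, Retnlg from 7.24 to 354 CPM in WT, and in KO from 0 UMIs to 545 CPM, at least 668-fold higher against a floor of 3 UMIs. The 10% of HSC/MPP-like cells with the most UMIs of 5 neutrophil genes held 88.9% of those UMIs in WT G-CSF and 88.1% in KO G-CSF. Without them, Retnlg was at 35.7 CPM in WT G-CSF and 56.4 in KO G-CSF, and S100a9 at 211.5 and 280.9. The secondary and tertiary granule list, proteins of late neutrophil precursors, had a relative median of -0.03 in WT and 0.42 in KO, and of -0.89 and -0.23 without those cells. In KO it was also negative, -0.21, at resolution 2.0. The primary granule list, whose members begin at the GMP stage, was at 0.00 in WT and -0.20 in KO.

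Between genotypes, the stem cell maintenance list was higher in KO HSC/MPP-like cells, by 0.17 (0.06 to 0.27) after PBS and 0.21 (0.10 to 0.31) after G-CSF (12 of 17 and 12 of 17 members above the median gene; percentiles 99.4 and 100). Mecom, a transcription factor of long-term HSC, went from 69.0 to 115 CPM after PBS (WT to KO; 1.67-fold (1.45 to 1.92) higher) and from 61.6 to 97.5 CPM after G-CSF (1.58-fold (1.37 to 1.83)). Esam, an adhesion molecule of HSC, was 1.69-fold and 1.47-fold higher, and Mllt3 1.32-fold and 1.43-fold. Hlf was 1.24-fold (1.16 to 1.32) higher after PBS and 1.07-fold (0.985 to 1.15) after G-CSF, the latter with an interval that spans 1. Procr (CD201), a further stem cell marker, went the other way and was 1.42-fold and 1.61-fold lower. Mecom, Esam, Mllt3, Hlf and Procr also served to name the class. S1pr1, a receptor that guides cells from tissue into blood and lymph, had 9.50 CPM in WT and 0.890 (3 UMIs) in KO after PBS, a level 10.7-fold (3.48 to 53.2) lower. After G-CSF it was 4.18-fold (1.96 to 10.2) lower in KO. Ptger3, a prostaglandin E receptor, was 4.67-fold (3.02 to 7.54) and 2.30-fold lower, and Hemgn 2.80-fold and 3.10-fold lower. Nkg7 (1.86-fold and 2.34-fold), Il1r1 (1.92-fold and 1.51-fold) and Prkg1 (3.38-fold and 1.74-fold) were lower in KO, while Selenom (4.42-fold and 2.62-fold) and Bex4 (2.66-fold and 2.98-fold) were higher. S phase genes were lower in KO, at -0.32 (-0.39 to -0.25) after PBS with 0 of 20 members above the median gene, and at -0.13 (-0.18 to -0.07) after G-CSF, where resolution 2.0 gave -0.03. The replication genes Pcna and Mcm5 were 1.34-fold and 1.51-fold lower after PBS. G2/M genes were at 0.13 after PBS and -0.14 after G-CSF. MHC class II genes were at -0.36 (-0.47 to -0.23) after PBS and -0.04 (-0.21 to 0.09) after G-CSF. The G-CSF receptor and STAT3 target list differed by -0.10 and -0.10, and the megakaryocyte-biased list by -0.01 and 0.05. Cxcr4 was 1.46-fold lower in KO after PBS and 1.36-fold higher after G-CSF. The secondary and tertiary granule list was at -0.74 (-0.90 to -0.61) after PBS, with 0 of 10 members above the median gene, and at 0.35 (0.17 to 0.56) after G-CSF, where the value was 0.18 without the neutrophil-rich cells and 0.10 at resolution 2.0. Ngp and Camp, antimicrobial granule proteins, were 2.87-fold and 1.89-fold lower after PBS and 2.57-fold and 2.81-fold higher after G-CSF, where the log2 ratio of Ngp was 0.11 without the neutrophil-rich cells. S100a9 of mature neutrophils was likewise lower in KO after PBS and higher after G-CSF. Ngp also fell in the whole library, from 6590.1 CPM in WT PBS to 2387 CPM in KO PBS, where neutrophil progenitor-like cells were fewer, and a background of their RNA in HSC/MPP-like cells was not tested after PBS. The primary granule list was at 0.14 after PBS, or -0.02 at resolution 2.0, and at 0.03 after G-CSF. The list of KMT2 complex members and coactivators moved little in all 4 comparisons: 0.11 and 0.09 with G-CSF in WT and KO (-0.03 in WT with the filter on low counts lifted for all genes), and 0.05 and -0.06 in KO after PBS and G-CSF.

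**Figure D3:**
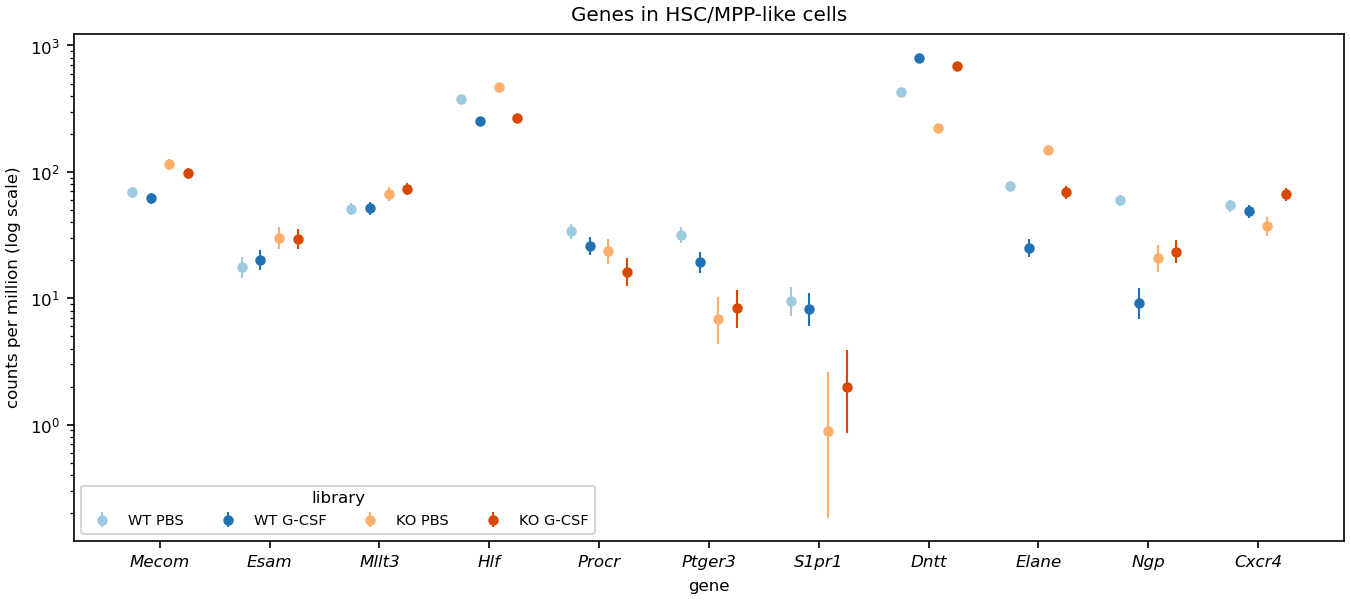
Level of selected genes in HSC/MPP-like cells of the 4 libraries in CPM (log axis), with exact 95% Poisson intervals as error bars. Dntt is higher after G-CSF in both genotypes, and Mecom is higher in KO, at 115 against 69.0 CPM after PBS.

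**Figure D4:**
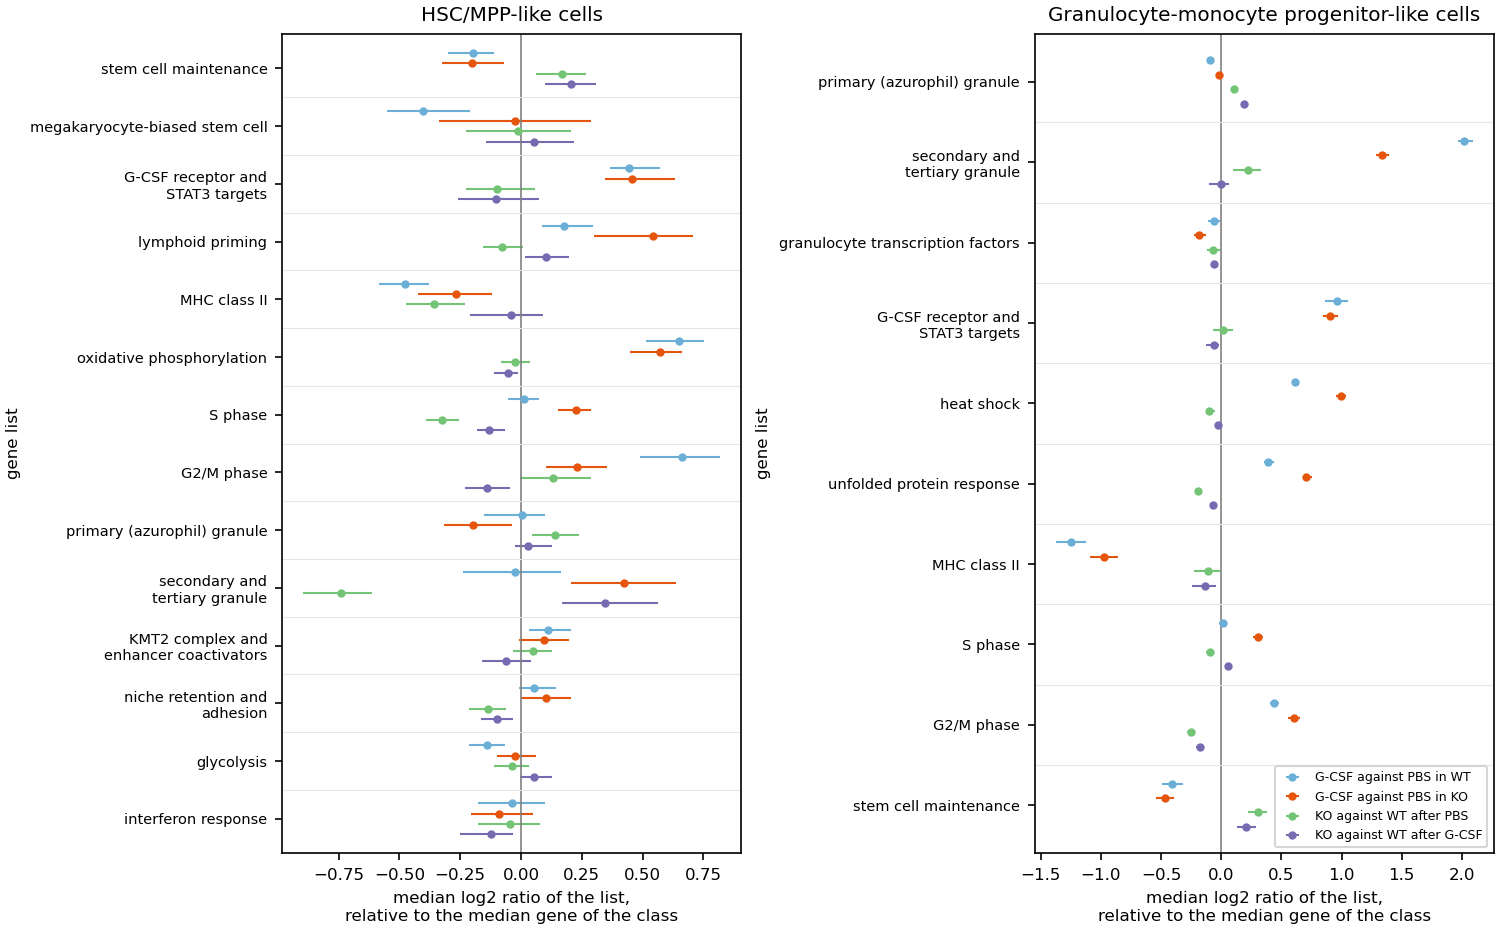
Median log2 ratio of each gene list relative to the median gene in HSC/MPP-like and GMP-like cells for the 4 comparisons, with 95% intervals from counting error as error bars. The STAT3 target list lies above 0 for G-CSF in both genotypes, and the HSC/MPP-like stem cell list lies below 0 for G-CSF and above 0 for KO against WT.

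In GMP-like cells, which come from different clusters after PBS and G-CSF, G-CSF went with higher levels of STAT3 target genes in both genotypes. The secondary and tertiary granule list was at 2.02 (1.96 to 2.09) in WT (9 of 11 members above the median gene) and 1.34 (1.28 to 1.39) in KO (10 of 11), but at 0.12 and -0.20 with the classes of resolution 2.0, so its size, and in KO its direction, rests on how the class is drawn. Lcn2, which sequesters iron from bacteria, went from 63.2 to 767 CPM in WT (14.0-fold higher) and from 49.6 to 671 CPM in KO (15.05-fold). S100a9, a calcium-binding protein abundant in neutrophils, was 17.9-fold and 11.7-fold higher, and Camp 5.71-fold and 2.59-fold (log2 ratio 0.61 in KO with doublets kept). Ltf (lactoferrin) was 1.82-fold lower in WT and 1.76-fold higher in KO, and with doublets kept its log2 ratio in WT was 1.79. In GMP-like cells after G-CSF, the ratio of Retnlg to S100a9 lay 10.2-fold (WT) and 4.78-fold (KO) below that in mature neutrophil-like cells. The ratio of Mmp9 lay 9.98-fold and 4.47-fold below, while those of S100a8 and Lcn2 differed by at most 1.31-fold. A background of RNA from mature neutrophil-like cells would keep all these ratios. The values thus argue against it as the source of most S100a9 there. A smaller background, or one for Camp and Ltf, was not tested. The primary granule list was at -0.09 in WT and -0.02 in KO (0.02 with TMM factors), with Elane 1.90-fold and 2.15-fold lower and Mpo 2.04-fold and 1.96-fold lower. Ctsg was 1.08-fold lower in WT and 1.05-fold higher in KO (log2 ratio -0.04 with doublets kept). The STAT3 list had 9 of 9 members above the median gene in WT and 9 of 9 in KO, with medians of 0.96 (0.86 to 1.05) in WT and 0.90 (0.85 to 0.97) in KO, or 0.48 and 0.60 with the filter on low counts lifted for all genes. Socs3 was 5.55-fold and 5.77-fold higher and Pim1, a kinase induced by cytokines, 2.26-fold and 1.88-fold. Ifitm1 went from 21.7 to 816 CPM in WT (43.3-fold (39.2 to 48.0)) and from 10.8 to 554 CPM in KO (57.0-fold (50.3 to 64.8)). Heat shock genes were at 0.61 (0.60 to 0.65) in WT and 1.00 (0.95 to 1.03) in KO, or 0.29 in WT when low-count members were included, and Hspe1, a mitochondrial chaperonin, was 4.69-fold and 3.56-fold higher. Unfolded protein response genes were at 0.39 (0.35 to 0.44) and 0.71 (0.68 to 0.75) (percentiles 86.9 and 99.8), with Hspa5, the main chaperone of the endoplasmic reticulum, 2.00-fold and 1.84-fold higher. G2/M genes were at 0.44 (0.41 to 0.48) in WT and 0.61 (0.55 to 0.65) in KO, with Plk1, a mitotic kinase, 2.68-fold and 2.67-fold higher. S phase genes were at 0.01 and 0.30, or -0.16 in WT with the filter on low counts lifted for all genes. The stem cell list was lower, -0.41 (-0.49 to -0.32) in WT and -0.47 (-0.54 to -0.40) in KO, though 0.01 in WT and -0.0058 in KO when low-count members were included. Cd34, a marker of early progenitors, was 4.24-fold and 5.01-fold lower (log2 ratios -1.12 and -1.17 with doublets kept) and Apoe 9.07-fold and 9.97-fold lower. The 3 measured MHC class II genes were lower, by -1.25 in WT and -0.98 in KO, or -0.03 and -0.10 with low-count members included. Among transcription factors, Cebpb, which drives emergency granulopoiesis, was 1.67-fold and 2.02-fold higher, Cebpa 1.64-fold and 1.17-fold lower, and the whole list at -0.06 and -0.19. Irf8, a factor of the monocyte and dendritic fate, was 4.12-fold and 2.71-fold lower, but its log2 ratios were 0.38 and 0.39 with doublets kept.

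Between genotypes, the class was made up differently after PBS: cluster 6 held 49.4% of GMP-like cells in WT and 64.6% in KO, and cluster 10 held 50.6% and 35.3%. After G-CSF, cluster 7 held 63.3% and 59.0%, and cluster 11 held 36.5% and 40.9%. The part of this mix in the differences given here was not tested. GMP-like cells of KO mice had higher levels of the primary granule list, by 0.11 (0.10 to 0.12) after PBS and 0.19 (0.18 to 0.19) after G-CSF, though at percentile 91.1 of random lists after PBS against 99.9 after G-CSF. Elane was 1.31-fold (1.3001 to 1.31) and 1.19-fold (1.19 to 1.198) higher, Prtn3 (proteinase 3) 1.104-fold and 1.16-fold, and Ctsg (cathepsin G) 1.05-fold and 1.22-fold. The secondary and tertiary granule list was higher in KO after PBS, 0.23 (0.10 to 0.33) with 8 of 11 members above the median gene (0.38 at resolution 2.0 and 0.094 with the filter on low counts lifted for all genes), and at -0.01 (-0.10 to 0.07) after G-CSF. Chil3, a secreted chitinase-like protein, was 2.39-fold and 1.23-fold higher, Camp 1.90-fold higher after PBS and 1.13-fold lower after G-CSF, and Fcnb 1.77-fold higher and 1.26-fold lower. G2/M genes were lower in KO, -0.25 (-0.29 to -0.22) after PBS (1 of 20 members above the median gene) and -0.18 (-0.21 to -0.15) after G-CSF (3 of 20), with Hmmr 1.27-fold and 1.55-fold lower. S phase genes were at -0.10 and 0.06. Unfolded protein response genes were at -0.19 (-0.22 to -0.17) after PBS and -0.06 (-0.08 to -0.05) after G-CSF, with Creld2 1.47-fold and 1.2999-fold lower, and heat shock genes at -0.10 and -0.02. The stem cell list, of which 6 of 18 members were measured in this class, was at 0.30 (0.22 to 0.38) and 0.21 (0.13 to 0.29), but at 0.11 and 0.028 with low-count members included, and Hoxa9 was 1.25-fold and 1.3999-fold higher. Cebpa, a master factor of granulocyte commitment, was 1.58-fold and 1.09-fold lower, Id2, an inhibitor of E proteins, 1.76-fold and 2.60-fold lower, and the granulocyte factor list was at -0.07 and -0.06. STAT3 list medians were 0.02 and -0.06, and those of MHC class II -0.11 and -0.13. Among single genes, Commd10 was 2.55-fold and 2.58-fold higher, Clec5a 3.21-fold and 1.48-fold lower, and Serpine2, a protease inhibitor, 2.58-fold and 3.37-fold lower.

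In the whole libraries, genes of the neutrophil lineage led the G-CSF comparisons. Retnlg, a resistin-like protein of mature neutrophils, went from 9.78 to 6163 CPM in WT and from 3.32 to 5556 CPM in KO, and Mmp8, a neutrophil collagenase, from 5.43 to 487 CPM and from 1.39 to 368 CPM. Camp, a gene of neutrophil precursors, went from 3939 to 266 CPM in WT and from 1806 to 270 CPM in KO, and Irf8 from 243 to 72.3 CPM and from 334 to 74.2 CPM. Between genotypes after PBS, Ly6g, the antigen of neutrophil maturation known as Gr1, went from 44.5 to 8.07 CPM (WT to KO) and Ngp from 6590.1 to 2387 CPM. Neutrophil progenitor-like cells made up 18.6% of WT PBS and 8.22% of KO PBS. Antibody tags on HSC/MPP-like cells had median counts for CD48, a marker of multipotent progenitors, of 441 in WT PBS, 494.5 in WT G-CSF, 192 in KO PBS and 150 in KO G-CSF. CD48 was lower in KO in the other named classes as well, with medians of 622 in WT PBS and 419 in KO PBS in GMP-like cells. CD117 medians in HSC/MPP-like cells were 175, 97, 157.5 and 59. Total antibody UMIs were 22137990, 23424101, 21234323 and 18490961 in the same order, and no correction between libraries was made.

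Peak sets of H3K4me1 were similar between genotypes. The base-pair Jaccard index (shared over combined length) of KO and WT was 73.9% after PBS and 77.8% after G-CSF in HSC/MPP, and 77.5% after either treatment in GMP. Between G-CSF and PBS it was 70.6% in WT and 71.7% in KO in HSC/MPP, and 72.0% and 72.8% in GMP, and WT PBS GMP and the WT reference from another experiment gave 76.2%. Of the KO H3K4me1 peaks, 86.9% and 89.9% had a WT peak in HSC/MPP after PBS and G-CSF, and 88.8% and 84.0% in GMP. The covered length in HSC/MPP was 305.2 Mb in WT PBS, 262.7 in WT G-CSF, 272.6 in KO PBS and 247.8 in KO G-CSF. In GMP it was 317.8, 278.1, 297.6 and 291.5 Mb. With peaks of a deposited -log10 q of at least 5, covered lengths in HSC/MPP were 27.7, 46.7, 11.1 and 36.4 Mb, and the Jaccard index of KO and WT was 35.2% after PBS and 65.9% after G-CSF.

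With all deposited peaks, H3K27ac sets overlapped less. In HSC/MPP the Jaccard index of KO and WT was 57.8% after PBS and 54.6% after G-CSF, and that of G-CSF and PBS 50.3% in WT and 49.9% in KO. In GMP the same indices were 28.3% and 25.8%, and 24.8% and 27.2%. WT PBS and KO G-CSF of GMP instead overlapped at 49.1%, and with the reference at 49.7% and 48.6%. GMP H3K27ac sets held 67456 peaks in WT PBS, 188059 in WT G-CSF, 139831 in KO PBS and 121489 in KO G-CSF, over 166.8, 190.8, 178.9 and 177.7 Mb. At a -log10 q of at least 5 they covered 74.6, 22.5, 22.7 and 53.02 Mb. Of the KO H3K27ac peaks, 58.8% and 58.5% had a WT peak in HSC/MPP and 34.1% and 50.5% in GMP, and at the stricter threshold 88.8% and 97.0%, and 96.1% and 81.3%. For H3K4me1 the latter percentages were lower, 84.3% and 89.4%, and 75.6% and 63.7%. The Jaccard index of KO and WT at that threshold was higher for H3K27ac than for H3K4me1 in HSC/MPP after PBS (62.0%) but not after G-CSF (64.0%), nor in GMP (28.7% and 37.4%, against 70.5% and 65.5% for H3K4me1).

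**Figure D5:**
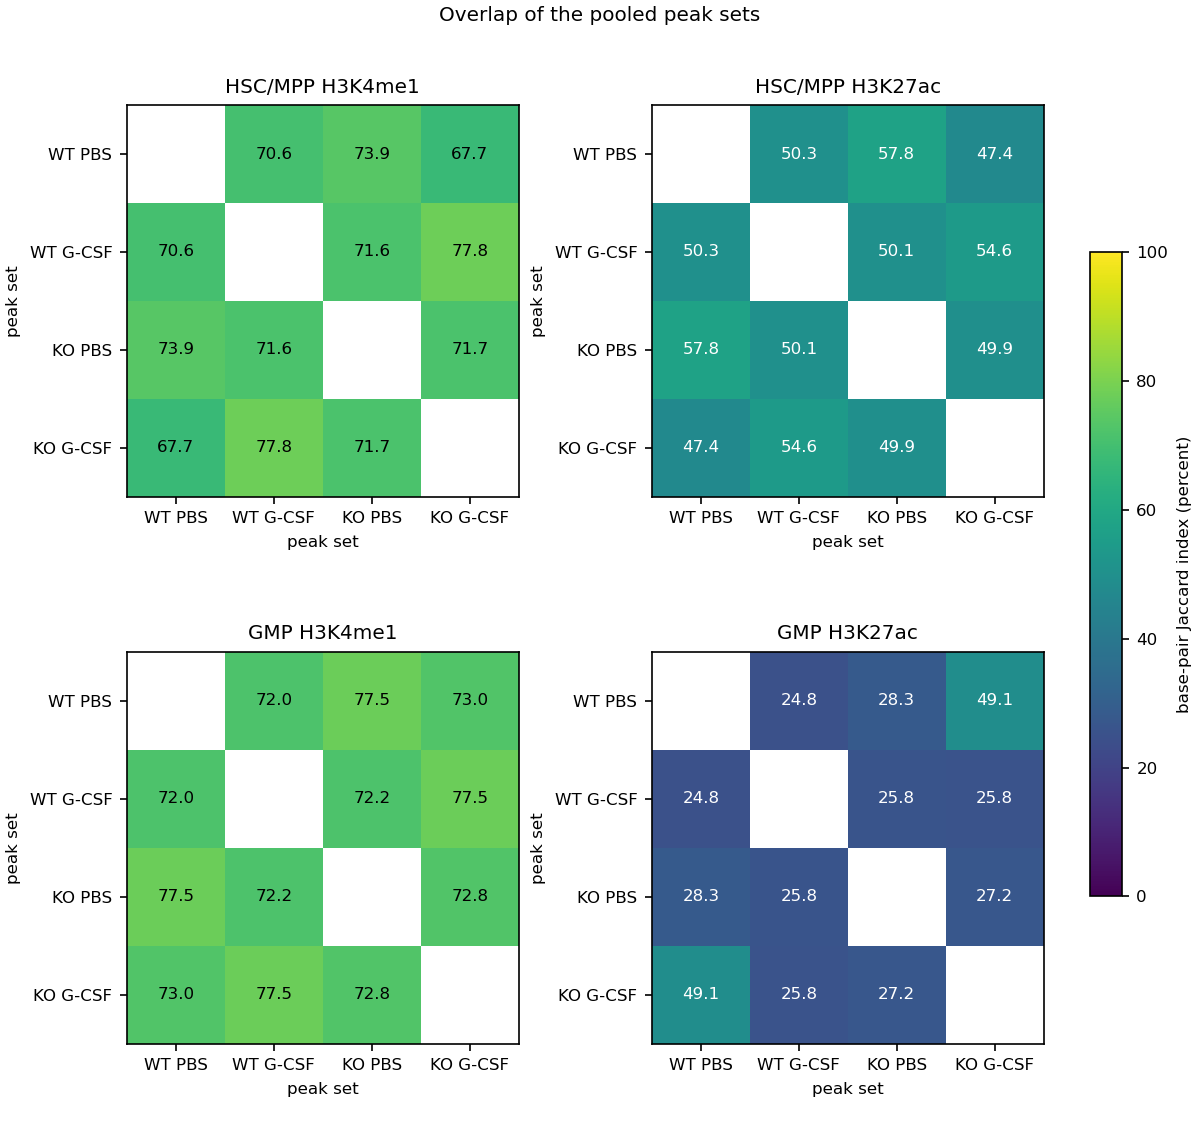
Base-pair Jaccard index in percent (color scale from 0 to 100) between each 2 of the 4 peak sets of the same mark and cell type, with all deposited peaks. H3K4me1 pairs lie between 67.7% and 77.8% and HSC/MPP H3K27ac pairs between 47.4% and 57.8%. GMP H3K27ac pairs lie between 24.8% and 28.3%, except WT PBS and KO G-CSF at 49.1%.

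A minority of the WT regions that differed with G-CSF also did so in KO. Of the WT H3K4me1 regions found only with G-CSF, 22.9% in HSC/MPP and 31.4% in GMP were also found only with G-CSF in KO. Of those found only with PBS, 22.4% and 20.7% were shared. Over all regions, 9.33% in HSC/MPP and 13.8% in GMP were found only with G-CSF in KO, and 12.7% and 10.4% only with PBS. Regions found in all 4 sets cannot differ with G-CSF and lower these shares over all regions. The opposite change in KO was found for 9.16% and 7.38% of the regions only with G-CSF and for 5.31% and 11.6% of those only with PBS. For H3K27ac the shared percentages were 17.7% and 21.8% in HSC/MPP, against 11.9% and 7.19% that went the opposite way. They lay below the shares over all regions in KO, 19.9% and 25.4%. In GMP 7.57% and 9.33% were shared, against 18.6% and 26.5% over all regions, and 12.5% and 25.8% went the opposite way. With equal numbers of peaks, 6.16% of the GMP regions only with G-CSF were shared and 6.14% went the opposite way. For those only with PBS it was 10.5% and 20.4%, so the opposite way led there only. H3K4me1 peaks over 1 kb from any transcription start site (TSS) that also carried H3K27ac, here called enhancer-like, made up 42.9% in WT PBS, 39.6% in WT G-CSF, 53.5% in KO PBS and 46.7% in KO G-CSF of HSC/MPP, and 37.1%, 50.8%, 49.1% and 48.4% in GMP. When at least 50% of the peak had to be covered these fell to 25.9%, 21.1%, 35.0% and 26.3%, and to 19.8%, 24.8%, 25.6% and 23.7%. The H3K27ac sets that enter these shares differed in size. In the same order of groups they held 73058, 74656, 93422 and 90554 peaks in HSC/MPP, and 67456, 188059, 139831 and 121489 in GMP. A larger set can overlap more peaks, and the shares were not computed with equal numbers, so they do not show a difference in enhancers apart from set size. In GMP, 66.2%, 59.8%, 58.4% and 59.1% of enhancer-like peaks overlapped WT open chromatin, against 27.1%, 29.7%, 28.6% and 29.96% of the distal H3K4me1 peaks without H3K27ac.

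At granulocyte genes (coordinates on mm10/GRCm38, 1-based, GENCODE vM21), Elane (chromosome 10, 79886247 to 79888215, TSS 79886247) had a GMP H3K27ac peak over its TSS in WT PBS and KO G-CSF but not in WT G-CSF and KO PBS. Within 50 kb of that TSS, H3K27ac peaks covered 56.2 kb in WT PBS, 22.5 in WT G-CSF, 24.4 in KO PBS and 66.1 in KO G-CSF. Mpo (chromosome 11, 87793581 to 87804413) and Irf8 (chromosome 8, 120736358 to 120756694) had the same arrangement at their TSS, with 62.3, 23.1, 19.3 and 60.8 kb around Mpo. H3K4me1 covered 84.7, 88.5, 83.2 and 87.5 kb around Elane in these groups. Of 21728 protein-coding genes, 466 had a GMP H3K27ac peak over the TSS in WT PBS and KO G-CSF only. The arrangement at Elane, Mpo and Irf8 thus recurs across the sets and was not shown to be particular to granulocyte genes. The TSSs of Cebpe (chromosome 14, 54710360 to 54712174), Csf3r (chromosome 4, 126024550 to 126044440) and S100a8 (chromosome 3, 90668978 to 90670035) lay under GMP H3K27ac in all 4 groups. In HSC/MPP, H3K27ac covered the TSS of Hlf (chromosome 11, 90336536 to 90390895) in all 4 groups and that of Mecom (chromosome 3, 29951296 to 30548008, TSS 30548008) in KO PBS only. The TSS of Vwf (chromosome 6, 125546774 to 125686679) lay under H3K4me1 in WT PBS and WT G-CSF but not in either KO set, while around Vwf H3K4me1 covered 61.1, 50.4, 58.6 and 55.2 kb in WT PBS, WT G-CSF, KO PBS and KO G-CSF.

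Ranked by the authors' deposited fold enrichment within a set, the leading HSC/MPP H3K4me1 peak of WT PBS with no KO PBS overlap lay in an intron of Kctd10 (chromosome 5, 114356138 to 114380093, 3.86-fold), and that of WT G-CSF with no KO G-CSF overlap in an intron of Cd82, a tetraspanin of quiescent HSC (chromosome 2, 93442063 to 93461935, 5.18-fold). For HSC/MPP H3K27ac, a peak beside the start of Arid2, a subunit of a chromatin remodelling complex, led WT PBS without KO PBS (chromosome 15, 96283613 to 96286797, intergenic, 8.71-fold), and a peak in the UTR of Cpsf2 led KO G-CSF without WT G-CSF (chromosome 12, 101974716 to 101977498, 11.3-fold). In GMP, the leading H3K4me1 peak of WT PBS without KO PBS was intergenic with Lyst as the nearest gene (chromosome 13, 13516552 to 13540359, 4.45-fold), and that of KO G-CSF without WT G-CSF lay in an intron of Tgfbi (chromosome 13, 56607426 to 56618442, 6.62-fold). For H3K27ac, Hspa8 led WT PBS without KO PBS (chromosome 9, 40797865 to 40805622, intron, 12.1-fold) and Pink1 led KO G-CSF without WT G-CSF (chromosome 4, 138324877 to 138328780, intergenic over the start site, 15.8-fold). Short peaks at Gm10801 (chromosome 2, 98662503 to 98662794 in KO PBS and 98662506 to 98662784 in WT G-CSF) led both other GMP H3K27ac comparisons between genotypes, at 10.8-fold and 15.6-fold. Median peak widths in the KO PBS and WT G-CSF sets were 969 and 728 bp, against 1351 bp in WT PBS and 790 bp in KO G-CSF, so width did not set these sets apart. No filter for regions of artefact signal was applied here. Several of these regions did not follow genotype alone, since listed peaks of the genotype that lacked them overlapped them under the other treatment: those at Kctd10, Arid2 and Lyst in KO G-CSF, that at Cd82 in KO PBS, and those at Tgfbi and Pink1 in WT PBS.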

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

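The tests of free RNA and of expression by the HSC/MPP-like cells themselves, and the test of Tpm3-rs7 against genotype, were chosen only after the results were seen. None of the differences between genotypes or treatments listed here was tested, because each group has 1 library or pooled set. No label ties a hashtag to an animal, so the hashtags were not used as replicates.

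Several results moved in opposite directions in the compared pairs. The granulocyte lineage share was lower in KO after PBS (log2 ratio -0.25) and higher after G-CSF (0.52), a gap of 0.77. GMP-like cells alone were higher in KO after both treatments (0.49 and 0.53), while neutrophil progenitor-like cells gave -1.18 and -0.13. The latter made up only 0.202% of WT G-CSF and 0.184% of KO G-CSF. The lineage also leaves out mature neutrophil-like cells, 64.2% of WT G-CSF and 61.1% of KO G-CSF. In HSC/MPP-like cells, Gdpd3 had 0.805 CPM in WT PBS, 34.4 in WT G-CSF, 52.5 in KO PBS and 1.48 in KO G-CSF, so that its G-CSF effects differed by -5.91 log2. By the same measure Gstp1 differed by 1.42, Hist1h2ap by 1.71 and Isg15 by -1.12. The arrangement of Gdpd3 was not particular to this class. In the whole libraries it had 3.10 and 3.56 CPM in high-Xist and high-Y cells of WT PBS and 77.0 and 68.9 in WT G-CSF. In KO PBS it had 40.1 and 35.4, and in KO G-CSF 10.3 and 11.5. In GMP-like cells Ahcy differed by 1.52, Gstp1 by 1.17 and Hist1h2ap by 2.12. Hist1h2ap there had 855 CPM in WT PBS, 462 in WT G-CSF, 364 in KO PBS and 868 in KO G-CSF. Some lists lay at opposite ends of their random lists in the compared pairs. In HSC/MPP-like cells, before the shift of the median gene was removed, the KO effect on G2/M genes went from 0.10 after PBS to -0.08 after G-CSF, a change of -0.18, and that on secondary and tertiary granule genes from -0.77 to 0.41, a change of 1.18. The KO effect on neutrophil progenitor markers went from -0.82 to 0.36, also a change of 1.18, and the G-CSF effect on them was -0.99 in WT and 0.14 in KO, 1.14 apart. In GMP-like cells the KO effect on these markers went from 0.07 to -0.12, a change of -0.18. GMP H3K27ac peaks with a -log10 q of at least 5 covered less with G-CSF in WT (log2 ratio -1.73) and more in KO (1.22), 2.95 apart.

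In every library the cells of 1 hashtag carried Xist, at 711 CPM in WT PBS, 470 in WT G-CSF, 909 in KO PBS and 460 in KO G-CSF, against 1.93, 2.39, 2.04 and 4.87 in the cells of the other hashtag, whose Y-linked genes were high. The hashtags were not used to form groups. The high-Xist cells carried Hashtag1 except in KO PBS, where they carried Hashtag2.

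Neutrophil transcripts in HSC/MPP-like cells rose with G-CSF, with S100a9 at 1579 CPM in WT and 1965 in KO. Expression by the HSC/MPP-like cells themselves would be free to depart from the proportions in mature neutrophil-like cells, but the ratios of 4 genes to S100a9 stayed within 1.39-fold of those proportions in both libraries, with and without the 10% of cells richest in neutrophil UMIs. Those 10% held 88.9% of these UMIs in WT G-CSF, which free RNA spread alike over all droplets would not give, so for them droplets that hold a progenitor and a neutrophil stay open as a candidate explanation. In the other cells free RNA stays open: the median percentage of a cell's UMIs that came from these genes was 0.0417 and 0.0454 under the 2 hashtags of WT G-CSF, within 1.09-fold of each other as in KO G-CSF, and 5 of 388 cells had none.

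The GMP H3K27ac sets of WT PBS and KO G-CSF overlapped more (Jaccard 49.1%) than any pair of the same genotype or treatment. A G-CSF effect of opposite direction in WT and KO was looked for in RNA. Of the genes with a TSS peak in WT PBS and KO G-CSF only, 276 were measured in GMP-like cells. The mean of their median RNA ratios toward the peaks was -0.00047 log2, against 0.018 for all genes, so no such effect was seen in their RNA. An effect on H3K27ac itself cannot be decided this way. The peak threshold was low, and GMP-like cells are clusters of the Lin-Kit+ sort, not sorted GMP. Lower enrichment in the KO PBS and WT G-CSF sets may play a part: their TSSs of 43 housekeeping genes lay under a peak less often, by 6.98 percentage points at the nearest, which is between the limits set in advance and cannot be told apart from none with 43 genes. Of all 21728 genes, 49.0% in WT PBS, 48.6% in WT G-CSF, 46.9% in KO PBS and 52.0% in KO G-CSF had such a peak, a smaller gap. Both sets were pooled from 3 replicates, but so was the WT reference, which overlapped WT PBS at 49.7%, and other differences in preparation and an exchange of labels were not tested.

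Tpm3-rs7 differed 27.4-fold between the hashtags of WT PBS (164.7 and 6.01 CPM in high-Xist and high-Y cells) and the other way in WT G-CSF (6.29 and 116.5), while the values were 129.1 and 128.4 in KO PBS and 242.3 and 128.3 in KO G-CSF. A difference between KO and WT does not by itself give the gap between hashtags within the WT libraries. The highest WT value exceeded the lowest KO value 1.28-fold, though the other WT values lay below every KO value. That comparison was chosen after these values were seen, so it cannot test such a difference. A variant carried by some of the pooled animals is a candidate explanation: the ratio was at least 20.8 in each of 7 classes of WT PBS. No label gives the strain background of single animals, so this stays a hypothesis.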

How the results depend on the processing

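The values with Scrublet calls, without mature neutrophil-like cells, per hashtag, without the neutrophil-rich cells and with the filter lifted for all genes come from tests chosen only after the results were seen. No paired analysis was possible because each group has 1 library or 1 set pooled by the authors. For the same reason no replicate was left out. Where a value moved or turned, the cause was not tested, except that leaving out a class raises the shares of the others. Depth limits the HSC/MPP-like sums to between 3370439 and 6213768 UMIs, and under thinning the HSC/MPP-like cluster stayed unnamed, so that no share of it is given there. Below, G-CSF in WT or KO stands for G-CSF against PBS, and KO after PBS or G-CSF for KO against WT.

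The lower Kmt2c level in KO held in 8 of 8 alternatives. The log2 ratio after PBS was -0.88 with TMM factors, -0.87 with DESeq2 size factors and -1.03 with a prior of 1 CPM, which gave -0.86 after G-CSF. Of 116 alternative log2 ratios of shares, 110 kept their direction, 77 of them within the counting interval. With stricter cell filters, HSC/MPP-like cells gave -1.502 (G-CSF in WT), -0.98 (G-CSF in KO) and -0.35 (KO after G-CSF), the granulocyte lineage gave -0.77 (G-CSF in KO) and the megakaryocyte-erythroid lineage gave -1.26 (G-CSF in KO). With doublets kept, HSC/MPP-like cells gave -1.21 (G-CSF in WT) and -0.92 (G-CSF in KO) and the granulocyte lineage gave -1.197 (G-CSF in WT) and -0.42 (G-CSF in KO). With Scrublet calls removed, the granulocyte lineage gave -1.26 (G-CSF in WT). At resolution 2.0, HSC/MPP-like cells gave -1.16 (G-CSF in WT) and -0.90 (G-CSF in KO) and the granulocyte lineage gave -0.72 (G-CSF in KO). At resolution 0.6, the granulocyte lineage gave -0.91 (G-CSF in WT) and -0.13 (G-CSF in KO). Without cell-cycle genes, HSC/MPP-like cells gave -1.0996 (G-CSF in WT) and the granulocyte lineage gave -1.71 (G-CSF in WT) and -0.95 (G-CSF in KO). Without mature neutrophil-like cells the direction turned, and HSC/MPP-like cells gave 0.55 (G-CSF in WT) and 0.72 (G-CSF in KO), the granulocyte lineage gave 0.084 (G-CSF in WT) and 0.74 (G-CSF in KO) and the megakaryocyte-erythroid lineage gave 0.27 (G-CSF in WT) and 0.28 (G-CSF in KO). In high-Xist cells alone, HSC/MPP-like cells gave -0.63 (G-CSF in WT) and -0.25 (G-CSF in KO), the granulocyte lineage gave -1.22 (G-CSF in WT) and -0.52 (G-CSF in KO) and the megakaryocyte-erythroid lineage gave -0.87 (G-CSF in WT), -0.52 (G-CSF in KO) and -0.39 (KO after PBS). In high-Y cells alone, HSC/MPP-like cells gave -1.24 (G-CSF in WT) and -1.05 (G-CSF in KO), the granulocyte lineage gave -1.58 (G-CSF in WT) and -0.74 (G-CSF in KO) and the megakaryocyte-erythroid lineage gave -1.57 (G-CSF in WT) and -1.72 (G-CSF in KO). After thinning, the granulocyte lineage gave -1.11 (G-CSF in WT) and -0.42 (G-CSF in KO).

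Of 440 alternative list medians, all relative to the median gene, 411 kept their sign and 343 stayed within the interval. With TMM factors, the GMP-like medians were primary granule -0.048 (G-CSF in WT), 0.017 (G-CSF in KO) and 0.12 (KO after PBS), heat shock 0.66 (G-CSF in WT) and S phase 0.053 (G-CSF in WT). Further values were G2/M phase 0.48 (G-CSF in WT). With the classes of resolution 2.0, the HSC/MPP-like medians were stem cell maintenance -0.075 (G-CSF in WT), STAT3 targets 0.58 (G-CSF in WT) and lymphoid priming -0.056 (G-CSF in WT), -0.052 (G-CSF in KO), 0.019 (KO after PBS) and 0.012 (KO after G-CSF). Further values were oxidative phosphorylation 0.49 (G-CSF in WT), S phase -0.15 (G-CSF in WT), -0.40 (KO after PBS) and -0.028 (KO after G-CSF) and G2/M phase 0.44 (G-CSF in WT) and 0.038 (G-CSF in KO). Others were primary granule -0.021 (KO after PBS), secondary and tertiary granule -0.40 (G-CSF in WT), -0.21 (G-CSF in KO) and 0.10 (KO after G-CSF) and glycolysis -0.10 (G-CSF in KO). With the classes of resolution 2.0, the GMP-like medians were primary granule -0.14 (G-CSF in WT), -0.13 (G-CSF in KO), 0.090 (KO after PBS) and 0.21 (KO after G-CSF), secondary and tertiary granule 0.12 (G-CSF in WT), -0.20 (G-CSF in KO) and 0.38 (KO after PBS) and granulocyte transcription factors -0.14 (G-CSF in WT) and -0.025 (KO after G-CSF). Further values were STAT3 targets 0.83 (G-CSF in KO), heat shock 0.68 (G-CSF in WT), 1.04 (G-CSF in KO) and -0.041 (KO after G-CSF) and S phase 0.079 (G-CSF in WT) and -0.055 (KO after PBS). Others were G2/M phase 0.45 (G-CSF in KO) and -0.15 (KO after G-CSF). With low-count list members included, the HSC/MPP-like medians were secondary and tertiary granule -0.60 (KO after PBS). With low-count list members included, the GMP-like medians were secondary and tertiary granule 1.201 (G-CSF in KO), STAT3 targets 0.65 (G-CSF in WT) and 0.73 (G-CSF in KO) and heat shock 0.29 (G-CSF in WT), 0.94 (G-CSF in KO), -0.035 (KO after PBS) and -0.0070 (KO after G-CSF). Further values were MHC class II -0.032 (G-CSF in WT), -0.098 (G-CSF in KO) and -0.029 (KO after G-CSF) and stem cell maintenance 0.012 (G-CSF in WT), -0.0058 (G-CSF in KO), 0.11 (KO after PBS) and 0.028 (KO after G-CSF). With the filter lifted for all genes, the HSC/MPP-like medians were lymphoid priming -0.012 (G-CSF in WT), oxidative phosphorylation 0.51 (G-CSF in WT) and S phase -0.13 (G-CSF in WT) and 0.15 (G-CSF in KO). Further values were G2/M phase 0.45 (G-CSF in WT), KMT2 complex -0.029 (G-CSF in WT) and niche retention and adhesion -0.081 (G-CSF in WT). Others were glycolysis -0.28 (G-CSF in WT) and -0.10 (G-CSF in KO) and interferon response -0.18 (G-CSF in WT). With the filter lifted for all genes, the GMP-like medians were primary granule -0.26 (G-CSF in WT), -0.15 (G-CSF in KO), 0.066 (KO after PBS) and 0.17 (KO after G-CSF), secondary and tertiary granule 1.81 (G-CSF in WT), 1.07 (G-CSF in KO) and 0.094 (KO after PBS) and granulocyte transcription factors -0.23 (G-CSF in WT) and -0.32 (G-CSF in KO). Further values were STAT3 targets 0.48 (G-CSF in WT) and 0.60 (G-CSF in KO), heat shock 0.12 (G-CSF in WT) and 0.81 (G-CSF in KO) and unfolded protein response 0.22 (G-CSF in WT), 0.58 (G-CSF in KO) and -0.24 (KO after PBS). Others were MHC class II -0.20 (G-CSF in WT) and -0.23 (G-CSF in KO), S phase -0.16 (G-CSF in WT), 0.17 (G-CSF in KO) and -0.14 (KO after PBS) and G2/M phase 0.27 (G-CSF in WT), 0.48 (G-CSF in KO) and -0.29 (KO after PBS). Further values were stem cell maintenance -0.16 (G-CSF in WT), -0.14 (G-CSF in KO), 0.061 (KO after PBS) and 0.014 (KO after G-CSF). Without the neutrophil-rich cells, the HSC/MPP-like medians were STAT3 targets 0.35 (G-CSF in WT), S phase 0.078 (G-CSF in WT) and secondary and tertiary granule -0.89 (G-CSF in WT) and -0.23 (G-CSF in KO).

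Of 1290 alternative values of single genes, 1264 kept their direction and 1047 stayed within the counting interval. With doublets kept, the reversed genes were Lcn2 at -0.15 (HSC/MPP-like, KO after G-CSF), Rag1 at -0.17 (HSC/MPP-like, KO after G-CSF), Ebf1 at -0.11 (HSC/MPP-like, KO after G-CSF), Ltf at 1.79 (GMP-like, G-CSF in WT), Ctsg at -0.043 (GMP-like, G-CSF in KO), Irf8 at 0.38 (GMP-like, G-CSF in WT), Irf8 at 0.39 (GMP-like, G-CSF in KO) and Birc5 at 0.0041 (GMP-like, KO after G-CSF). Without the neutrophil-rich cells, Csf3r was at -0.017 (HSC/MPP-like, G-CSF in KO).

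Of peak results, those that stayed within the counting interval were 9 of 32 shares of KO peaks with a WT peak, 18 of 32 Jaccard indices, 0 of 8 shares of WT regions found only with G-CSF, 0 of 8 shares of those found only with PBS and 0 of 8 enhancer-like shares. The 18 indices include 8 from the setting with at least 50% of a peak covered. That setting does not enter the index, so these 8 could not move. Within 1.5-fold stayed 1 of 19 numbers of peaks and 1 of 19 covered lengths; these sizes have no direction to keep. At a -log10 q of at least 5, the share of KO peaks with a WT peak was 84.3% (after PBS) and 89.4% (after G-CSF) for HSC/MPP H3K4me1, 88.8% (after PBS) and 97.0% (after G-CSF) for HSC/MPP H3K27ac, 75.6% (after PBS) and 63.7% (after G-CSF) for GMP H3K4me1 and 96.1% (after PBS) and 81.3% (after G-CSF) for GMP H3K27ac. The Jaccard index of KO and WT was then 35.2% (after PBS) and 65.9% (after G-CSF) for HSC/MPP H3K4me1, 62.0% (after PBS) and 64.0% (after G-CSF) for HSC/MPP H3K27ac, 70.5% (after PBS) and 65.5% (after G-CSF) for GMP H3K4me1 and 28.7% (after PBS) and 37.4% (after G-CSF) for GMP H3K27ac. With at least 50% of the peak covered, the share of KO peaks with a WT peak was 82.6% (after PBS) and 86.1% (after G-CSF) for HSC/MPP H3K4me1, 48.8% (after PBS) and 48.7% (after G-CSF) for HSC/MPP H3K27ac, 83.9% (after PBS) and 77.5% (after G-CSF) for GMP H3K4me1 and 27.1% (after PBS) and 36.2% (after G-CSF) for GMP H3K27ac. Of the WT regions found only with G-CSF, KO then shared 26.4% for HSC/MPP H3K4me1, 15.1% for HSC/MPP H3K27ac, 33.4% for GMP H3K4me1 and 4.54% for GMP H3K27ac. Of those found only with PBS it shared 28.4% for HSC/MPP H3K4me1, 28.4% for HSC/MPP H3K27ac, 24.1% for GMP H3K4me1 and 10.1% for GMP H3K27ac. With equal numbers of peaks, KO peaks with a WT peak were 88.2% (after PBS) and 89.3% (after G-CSF) for HSC/MPP H3K4me1, 68.5% (after PBS) and 66.8% (after G-CSF) for HSC/MPP H3K27ac, 86.2% (after G-CSF) for GMP H3K4me1 and 57.4% (after PBS) and 49.3% (after G-CSF) for GMP H3K27ac. The Jaccard index was then 59.5% (after PBS) and 56.4% (after G-CSF) for HSC/MPP H3K27ac, 77.7% (after G-CSF) for GMP H3K4me1 and 33.6% (after PBS) and 32.2% (after G-CSF) for GMP H3K27ac. Of the WT regions found only with G-CSF, KO then shared 25.9% for HSC/MPP H3K4me1, 15.4% for HSC/MPP H3K27ac, 29.6% for GMP H3K4me1 and 6.16% for GMP H3K27ac. Of those found only with PBS it shared 21.0% for HSC/MPP H3K4me1, 17.7% for HSC/MPP H3K27ac, 23.3% for GMP H3K4me1 and 10.5% for GMP H3K27ac. On chromosomes 1 to 19 alone, the index that moved was 74.1% (after PBS) for HSC/MPP H3K4me1. Enhancer-like shares with at least 50% of the peak covered were HSC/MPP 25.9% (WT PBS), 21.1% (WT G-CSF), 35.0% (KO PBS) and 26.3% (KO G-CSF) and GMP 19.8% (WT PBS), 24.8% (WT G-CSF), 25.6% (KO PBS) and 23.7% (KO G-CSF). HSC/MPP H3K4me1 at a -log10 q of at least 5 kept 3569 peaks over 36.4 Mb (KO G-CSF), 902 peaks over 11.1 Mb (KO PBS), 4606 peaks over 46.7 Mb (WT G-CSF) and 1916 peaks over 27.7 Mb (WT PBS). HSC/MPP H3K27ac at a -log10 q of at least 5 kept 6891 peaks over 22.8 Mb (KO G-CSF), 7491 peaks over 36.3 Mb (KO PBS), 8213 peaks over 29.3 Mb (WT G-CSF) and 7570 peaks over 45.2 Mb (WT PBS). GMP H3K4me1 at a -log10 q of at least 5 kept 14221 peaks over 118 Mb (KO G-CSF), 7571 peaks over 79.5 Mb (KO PBS), 9633 peaks over 90.0 Mb (WT G-CSF), 6405 peaks over 80.3 Mb (WT PBS) and 2999 peaks over 43.2 Mb (WT reference). GMP H3K27ac at a -log10 q of at least 5 kept 12489 peaks over 53.02 Mb (KO G-CSF), 9936 peaks over 22.7 Mb (KO PBS), 11281 peaks over 22.5 Mb (WT G-CSF), 12291 peaks over 74.6 Mb (WT PBS) and 6925 peaks over 32.1 Mb (WT reference).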

Other observations

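No hypothesis of its own is tested in this part; the lists and tags were chosen for description after their values were seen.

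Further gene groups in HSC/MPP-like cells are described here. The niche retention and adhesion list does not hold retention genes alone. Among its members is S1pr1, which guides cells from tissue into blood and lymph and was itself lower in KO. The list had medians relative to the median gene of 0.06 (-0.01 to 0.14) for G-CSF in WT and 0.10 (0.00 to 0.20) in KO. It was lower in KO than in WT, at -0.13 (-0.21 to -0.06) after PBS (5 of 18 members above the median gene, percentile 0.950) and -0.10 (-0.16 to -0.03) after G-CSF (6 of 18, percentile 4.69). Glycolysis genes were at -0.14 and -0.03 for G-CSF in WT and KO and at -0.04 and 0.05 for KO after PBS and G-CSF. Interferon response genes were at -0.04, -0.09, -0.04 and -0.12 in the same order, although Ifitm1 was much higher after G-CSF. With the filter on low counts lifted for all genes, the values for G-CSF in WT were -0.081 for niche retention, -0.28 for glycolysis and -0.18 for interferon response genes.

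The share of TSSs under an H3K4me1 peak moved with treatment more than with genotype. Of 21728 protein-coding genes, H3K4me1 peaks covered the TSS of 23.7% in WT PBS, 34.3% in WT G-CSF, 19.97% in KO PBS and 32.05% in KO G-CSF of HSC/MPP, and of 27.7%, 35.6%, 24.5% and 40.0% in GMP. The WT GMP reference gave 26.3%. In the same order of groups, H3K4me1 peaks within 1 kb of a TSS numbered 26399, 25859, 26506 and 25615 in HSC/MPP. In GMP they numbered 26109, 25482, 25968 and 25275. These numbers were slightly lower with G-CSF, so peaks near TSSs did not become more frequent.

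Antibody tags in GMP-like cells had median CD16/32 counts of 219 in WT PBS, 361 in WT G-CSF, 178 in KO PBS and 277 in KO G-CSF, and median CD34 counts of 21, 8, 20 and 6. CD41, an integrin of megakaryocytes, had medians of 38, 62, 10 and 12 in megakaryocyte-like cells. In mature neutrophil-like cells Gr1 had medians of 1545 and 858, and CD11b of 262 and 198, in WT and KO G-CSF. These counts were not corrected between libraries, and KO G-CSF held fewer antibody UMIs (18490961 against 23424101 in WT G-CSF) over more barcodes (8284 against 6829).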
